A study of Homo sapiens with 6 samples.

How the data were processed

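Polyadenylated RNA of PC3 cells was sequenced as stranded libraries with unique molecular identifiers on an Illumina NovaSeq instrument. There were 3 libraries with overexpression of hsa_circ_0070512 and 3 with the empty vector. Per the labels, the libraries numbered 1, 2 and 3 of each group are from days 5, 7 and 9 after transfection. The submitters' processing notes list cutadapt 1.9, UMI-tools, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2, edgeR and the GRCh38 build, without the role or settings of each.

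The deposited count matrix holds expected counts (expected_counts), estimated read counts per gene in whole numbers, for 60612 genes. The deposited expression table holds FPKM (fpkm) and the same counts for 33988 genes, per the file headers. Counts were identical in both tables, and over 10106 genes with more than 500 counts in every library the ratio of count to FPKM within a gene was nearly constant across libraries after scaling (median coefficient of variation 0.03%). The FPKM values are therefore no independent measurement, and which was derived from the other was not determined. Of the gene identifiers in the expression table, 33855 were found in the reference names.

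Totals ran from 45126486 to 54744920 estimated counts per library. A floor of 3 counts per library was used for genes at 0. Floors cover counting error only. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic, so it includes spread between libraries. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood F-tests in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were overexpression against vector with group alone, the slope per day with group as a term, and the interaction of group and day. All p-values are 2-sided unless stated. CPM were computed from TMM-scaled library sizes (factors 0.976 to 1.018), and the floors from unscaled totals.

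Because the numbers give a shared day, pairing was checked: correlations of residuals between overexpression and vector libraries of the same day were -0.036, -0.042 and 0.014, against -0.036 to 0.071 for different days. The fit with day as a block is given beside each result whose call it changes or whose count it moves by more than 1.5-fold.

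The comparisons, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The named genes were the 12 largest changes in each direction among called genes with a symbol, a mean of at least 2 CPM and the same sign on all 3 days, up to 4 members of each list by smallest p with a mean of at least 2 CPM, every Hedgehog member with a mean of at least 0.5 CPM, and the 4 genes of smallest interaction p. For the slope, 6 genes per direction were to be named among those called, and none was called. Some genes that meet the rule are not reported here, and they are left out of the counts of named genes. The 24 lists covered Hedgehog, DNA replication, mitosis, mesenchymal, epithelial, interferon, NF-kappaB, p53, ATF4, ER chaperone, hypoxia and glycolysis, cholesterol synthesis, androgen receptor and luminal, YAP/TAZ, Wnt, neuroendocrine, immediate-early and MAPK, histone, mitochondrially encoded, ribosomal protein, oxidative phosphorylation, fibroblast, leukocyte and endothelial genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log CPM with a prior count of 2. The circular RNA was not looked for through any gene symbol, and no value is given for it.

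Alternatives were RLE or library size scaling, no filter or a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with a pseudocount of 1 or 0.1, robust fitting, an adjusted p of 0.1, an absolute log2 fold change of at least 1, day as a block, each library left out in turn, and, for lists, an estimated correlation and fry. Chosen after seeing the data were the fits without overexpression replicates 1 and 2 together and the enrichment of GO and KEGG terms of 10 to 300 genes among called genes, by a 1-sided hypergeometric test against tested genes with an annotation (14275 for GO, 5694 for KEGG). The enrichment code gave 0 terms in 20 random sets of 200 genes for each source. Random sets are not made of genes that move together, so this does not check the adjusted p of terms with correlated members.

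In simulated data of the same design with 19721 genes tested, changes were added to 82, 56 and 62 genes. In these data edgeR recovered 29.3%, 62.5% and 80.6% of the genes changed by 0.5, 1 and 2 log2 units in that order. Of its calls 9.2% were genes with no added change, against 22.9% for DESeq2 and 21.1% for edgeR with day as a block. Genes were drawn independently and without a day effect. These shares therefore need not hold for the real libraries, and they do not rank the fit with day as a block. Exons and 3' untranslated regions came from the GENCODE annotation. Further computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

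Several tests in the closing part were reworked after first results were seen. A first version of the tests on overexpression replicates 1 and 2 averaged those libraries against the other 4, which groups samples by the outcome, and it was replaced by values per library against the vector mean. The narrower tests of read-through genes and of overlapping genes with large changes were added after the wider test of all overlapping genes had been seen.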

Results

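The series holds 6 RNA sequencing libraries from PC3, an established human prostate cancer cell line that grows without androgen. Cells carried either a vector overexpressing the circular RNA hsa_circ_0070512 (3 libraries) or the empty vector (3 libraries). The libraries numbered 1, 2 and 3 were collected at days 5, 7 and 9 after transfection, 1 library per group and day. Each group's spread therefore covers both time and replicate variation, and the p-values given here measure effects against the spread between libraries of different days. The total estimated count was 54744920, 50517468 and 45126486 in overexpression replicates 1, 2 and 3. It was 51114200, 52018296 and 52721783 in vector replicates 1, 2 and 3. A count of 3, taken as the detection floor, corresponded to between 0.0548 and 0.0665 CPM per library, computed from the library total. All other CPM (counts scaled to a common library size) used TMM-scaled library sizes. This floor covers counting error only. The tables list genes, and neither was matched to the circular RNA itself, so no value is given for it. Values are mean CPM ± SD with n = 3 per group. Log2 fold changes are overexpression minus vector ± SE, and positions are on GRCh38.

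The first comparison asked which genes differed between cells overexpressing the circular RNA and cells with the empty vector. PPP3CA, which encodes the catalytic alpha subunit of the phosphatase calcineurin, was higher in every overexpression library. It was at 499 ± 7.44 CPM against 49.1 ± 3.26 CPM, a ratio of 10.2 (ENSG00000138814, chromosome 4, 101023409 to 101348278, minus strand, log2 fold change 3.34 ± 0.07, edgeR adjusted p = 3.41e-09). Reads of the overexpression construct counted at PPP3CA cannot be told apart from a rise of the gene itself. CCND2, which encodes the cell cycle regulator cyclin D2, rose from 11.3 ± 0.975 to 34.6 ± 2.79 CPM (ENSG00000118971, chromosome 12, 4269771 to 4305350, log2 fold change 1.61 ± 0.10, edgeR adjusted p = 7.35e-05). PLAU, which encodes the urokinase plasminogen activator, fell from 59.1 ± 3.67 to 16.4 ± 1.28 CPM (ENSG00000122861, chromosome 10, 73909177 to 73917494, log2 fold change -1.85 ± 0.09, edgeR adjusted p = 8.31e-06). The glucose transporter gene SLC2A3 fell by 1.62 on the log2 scale (2.39 ± 0.324 against 7.38 ± 0.798 CPM, edgeR adjusted p = 0.0034), and GPNMB, which encodes a transmembrane glycoprotein, fell by 1.72 (10.5 ± 1.40 against 34.6 ± 9.06 CPM, edgeR adjusted p = 0.00174). All 5 genes kept their direction on each of the 3 days, as the naming rule requires. They kept their call with day as a block, with block adjusted p from 1.33e-06 for PPP3CA to 0.0184 for SLC2A3.

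In all, 461 of 20352 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 221 higher and 240 lower. Each of the 461 had the same sign on all 3 days, which their selection in the same libraries largely fixes. Most changes were small: the median absolute log2 fold change of the called genes was 0.447, 314 were below 1.5-fold, and 66 (29 higher, 37 lower) had an absolute log2 fold change of at least 1. With day as a block, 74 genes were called (34 higher, 40 lower), all among the 461. Both groups hold the same days, so the lost calls do not show a difference of day between the groups. The block also leaves fewer degrees of freedom for the error. Scaling to library size alone gave 500 genes with a different balance, 322 higher and 178 lower. The count moved with single libraries: it was 78 without overexpression replicate 1, 175 without overexpression replicate 2, 116 without overexpression replicate 3, 511 without vector replicate 1, 95 without vector replicate 2 and 54 without vector replicate 3.

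**Figure D1:**
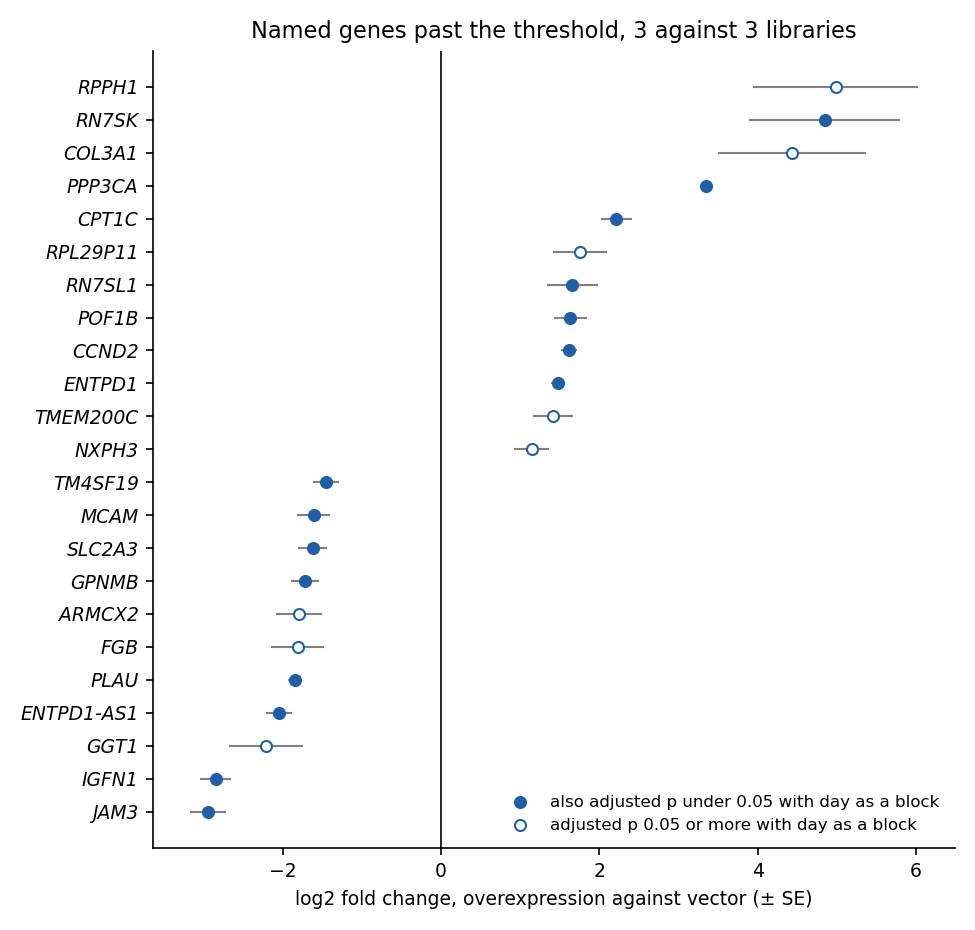
Log2 fold change (overexpression minus vector, ± SE) of the 12 largest changes in each direction among called genes with a symbol, a mean of at least 2 CPM and the same sign on all 3 days, each point 1 gene and filled where the call was kept with day as a block; BIVM-ERCC5 is left out because it was at 0 in every overexpression library. PPP3CA stands at 3.34 with a small error, and RPPH1, RN7SK and COL3A1 have the widest errors among the higher genes.

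Of the other genes with large increases, CPT1C, which encodes a member of the carnitine palmitoyltransferase family, rose by 2.22 ± 0.19 on the log2 scale (6.90 ± 0.781 against 1.48 ± 0.157 CPM, edgeR adjusted p = 0.000617). POF1B rose by 1.63 ± 0.21 (5.33 ± 0.699 against 1.72 ± 0.256 CPM, edgeR adjusted p = 0.00662). TMEM200C at 1.41, NXPH3 at 1.14 and the ribosomal protein pseudogene RPL29P11 at 1.75 were called in the comparison but lost the call with day as a block (block adjusted p = 0.076, 0.109 and 0.122). Among the large decreases, IGFN1 fell by 2.85 ± 0.20 (1.37 ± 0.286 against 9.90 ± 0.742 CPM, edgeR adjusted p = 0.000144) and TM4SF19 by 1.45 ± 0.17 (means 4.0 and 10.9 CPM, edgeR adjusted p = 0.0034). GGT1 at -2.21, the fibrinogen gene FGB at -1.81 and ARMCX2 at -1.80 lost the call with day as a block (block adjusted p = 0.0687, 0.109 and 0.0799). ARMCX2, FGB, GGT1, NXPH3, RPL29P11 and TMEM200C were each called in 3 or fewer of the 6 fits that left out 1 library. All 6 genes lost the call without overexpression replicate 1 and without vector replicate 3, with adjusted p up to 0.107, 0.107, 0.164, 0.121, 0.144 and 0.133 in that order.

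Several of the largest changes lay at genes whose exons overlap a neighbour that moved the other way in the group means. ENTPD1, which encodes the ectonucleotidase CD39, rose by 1.48 ± 0.09 on the log2 scale (66.8 ± 5.34 against 23.9 ± 2.43 CPM, edgeR adjusted p = 7.35e-05), while ENTPD1-AS1 on the opposite strand fell by 2.04 ± 0.16 (13.1 ± 3.53 against 54.1 ± 5.19 CPM, edgeR adjusted p = 0.000334). ENTPD1 gained 42.82 CPM, the CPM of its antisense neighbour fell by 41.01, and the log2 ratio of their summed CPM was 0.03. The read-through gene BIVM-ERCC5 had 0 counts in all 3 overexpression libraries against 27.8, 0.414 and 25.8 CPM in vector replicates 1, 2 and 3 (edgeR adjusted p = 0.0378). Its vector mean of 18.0 ± 15.3 CPM was 271 times the floor of 0.0665 CPM per library. This ratio does not hold for vector replicate 2. BIVM-ERCC5 was called in 1 of the 6 fits that left out 1 library, the fit without vector replicate 2 (adjusted p up to 0.133). BIVM and ERCC5, which overlap it, gained 23.58 CPM together against its loss of 17.99 CPM. The adhesion molecule genes JAM3 (fell by 2.95 ± 0.23, edgeR adjusted p = 0.000242) and MCAM (fell by 1.61 ± 0.21, edgeR adjusted p = 0.00684) overlap NCAPD3 and CBL. In the group means these gained 12.97 and 11.47 CPM while JAM3 lost 4.11 and MCAM 5.34 CPM. The partner gains did not hold on day 7. There the summed CPM of JAM3 and NCAPD3 was 136.8 with overexpression against 150.4 with vector. That of MCAM and CBL was 155.9 against 184.4, and both drops exceeded those of JAM3 and MCAM themselves. Whether the authors' counting used strand is not stated.

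**Figure D2:**
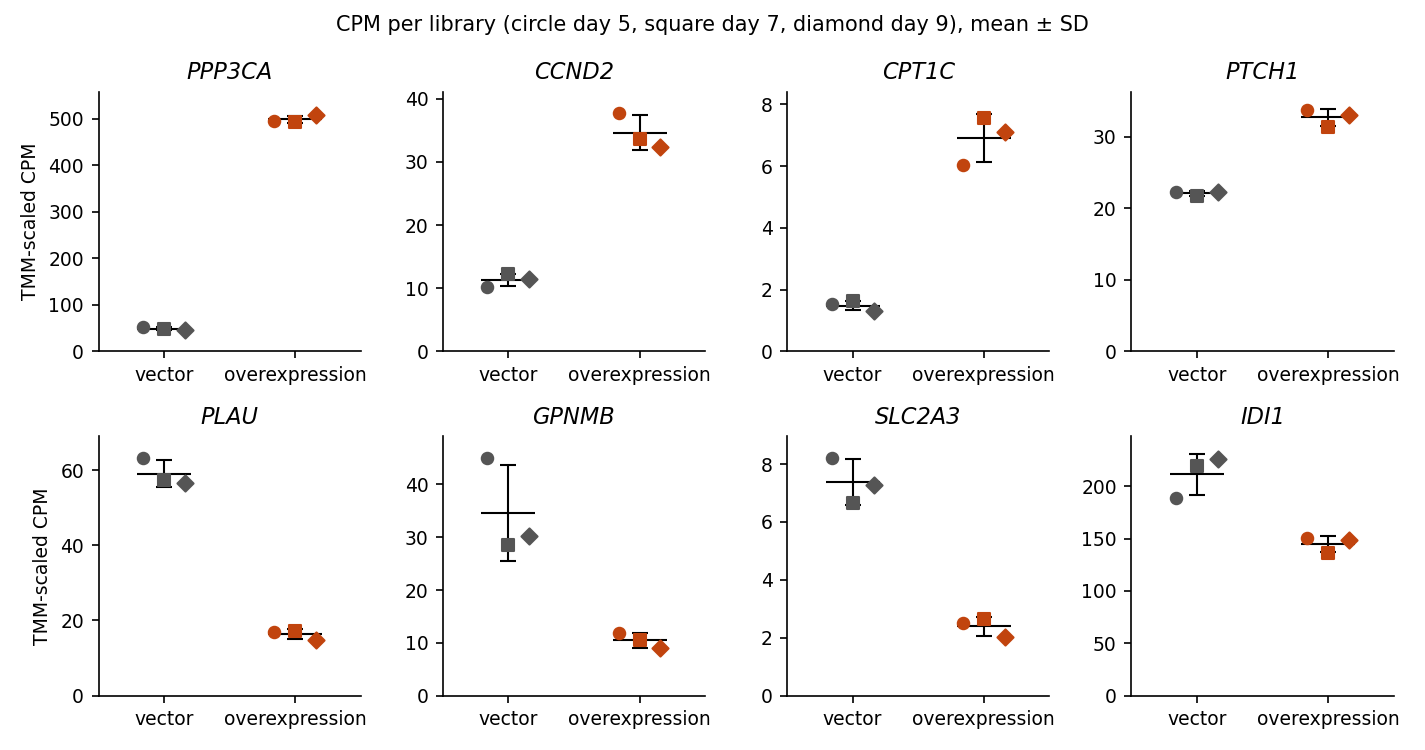
CPM in each library for 8 genes, with circles for day 5, squares for day 7 and diamonds for day 9, and the group mean ± SD (n = 3). The overexpression libraries lie apart from the vector libraries on every day for PPP3CA, CCND2, CPT1C, PTCH1, PLAU, GPNMB, SLC2A3 and IDI1.

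Overexpression replicates 1 and 2 stood apart from the other 4 libraries for several noncoding RNAs and collagens. RN7SK, the 7SK RNA that holds the elongation factor P-TEFb inactive, was at 20.3 and 12.3 CPM in overexpression replicates 1 and 2, at 0.741 in replicate 3 and at no more than 0.547 in any vector library (log2 fold change 4.85 ± 0.95, edgeR adjusted p = 0.0326). RPPH1, the RNA of ribonuclease P, was at 10.2, 6.98 and 0.305 CPM in overexpression replicates 1, 2 and 3 and at no more than 0.254 in any vector library (log2 fold change 4.99 ± 1.04, edgeR adjusted p = 0.0394, block adjusted p = 0.14). RN7SL1, the RNA of the signal recognition particle, was at 29.7, 26.7 and 10.6 CPM against no more than 8.44 (log2 fold change 1.66 ± 0.33, edgeR adjusted p = 0.0326). COL3A1, a fibrillar collagen gene in the list of fibroblast markers, was at 6.81, 5.32 and 0.24 CPM against no more than 0.254 (log2 fold change 4.44 ± 0.94, edgeR adjusted p = 0.0407, block adjusted p = 0.0955). RN7SK, RPPH1, RN7SL1 and COL3A1 were each called in 1 of the 6 fits that left out 1 library, the fit without overexpression replicate 3. In the others their adjusted p reached 0.158, 0.16, 0.156 and 0.181. Without overexpression replicates 1 and 2 together, chosen after seeing the data, 22 genes were called, 16 of them among the 461.

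**Figure D3:**
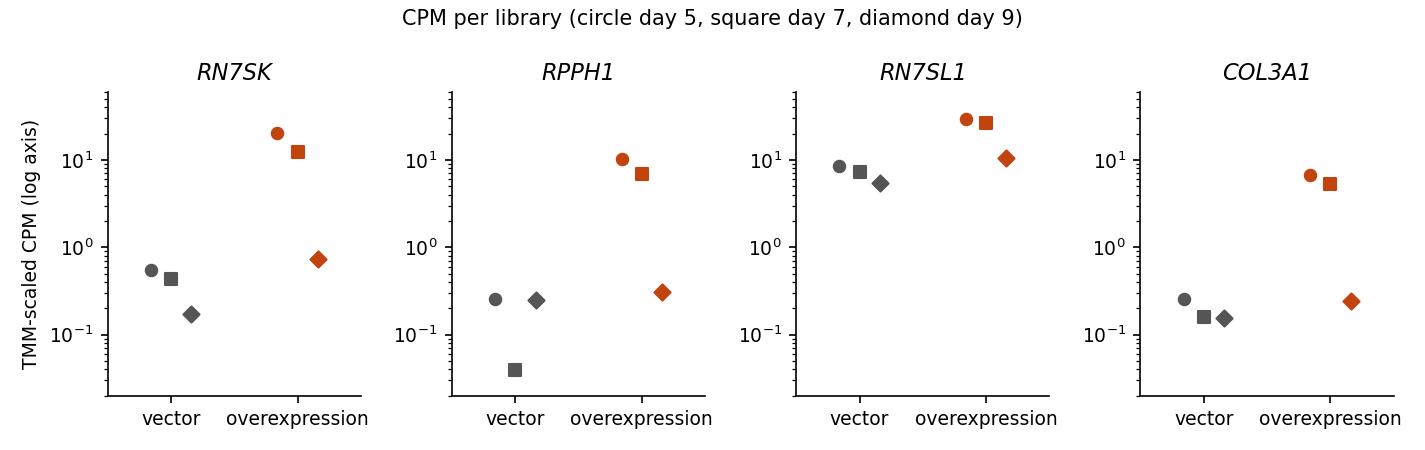
CPM of RN7SK, RPPH1, RN7SL1 and COL3A1 in each of the 6 libraries, on a log axis. Overexpression replicates 1 and 2 lie above all vector libraries, while overexpression replicate 3 is at 0.741 CPM for RN7SK and 0.24 CPM for COL3A1.

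Genes of cholesterol synthesis were mostly lower, though the test of the list depended on the correlation assumed between genes. Of 20 members tested, 8 fell and none rose, with 17 lower when adjusted over the list alone, and 19 of 20 had a negative log2 fold change (median -0.33). NSDHL fell by 0.56 ± 0.09 on the log2 scale (25.4 ± 1.62 against 37.4 ± 2.76 CPM), IDI1 by 0.54 ± 0.08 (144.9 ± 7.69 against 211 ± 19.9 CPM) and the squalene epoxidase gene SQLE by 0.53 ± 0.08 (97.52 ± 7.50 against 140.6 ± 10.2 CPM). The list's camera test with a preset correlation gave adjusted p = 3.32e-10, and adjusted p = 9.88e-09 with day as a block. The estimated correlation of this list was 0.473, far above the preset 0.01. With it the camera test gave adjusted p = 0.75, and fry gave adjusted p = 0.0772. With day as a block 1 member, NSDHL, kept its own call (block adjusted p = 0.045), while IDI1 and SQLE were at 0.0504 and 0.0678. IDI1 lost its call without vector replicate 3 (adjusted p = 0.0714). SQLE lost its call without overexpression replicate 3 or vector replicate 3 (adjusted p up to 0.0657). NSDHL lost its call without overexpression replicate 1, vector replicate 2 or vector replicate 3 (up to 0.0982).

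Hedgehog pathway genes were followed by the study, so this list is not independent of it. Of 17 members tested, 3 rose and none fell, with 5 higher and 1 lower when adjusted over the list alone. PTCH1, a Hedgehog receptor that is also induced by the pathway, rose by 0.57 ± 0.08 on the log2 scale (32.7 ± 1.20 against 22.1 ± 0.332 CPM, edgeR adjusted p = 0.00719, block adjusted p = 0.045). SMO, the signal transducer, rose by 0.44 ± 0.07 (55.5 ± 3.79 against 41.0 ± 2.21 CPM, edgeR adjusted p = 0.0218, block adjusted p = 0.0837), and SUFU, a negative regulator, by 0.41 ± 0.09 (26.3 ± 2.11 against 19.7 ± 0.484 CPM, edgeR adjusted p = 0.0421, block adjusted p = 0.134). The remaining members did not pass, and their values follow where reported. The ligand SHH was at 0.83 (edgeR adjusted p = 0.0821) and the transcription factors GLI2, GLI1 and GLI3 at 0.67, -0.09 and -0.18. KIF7 was at -0.58, EVC2 at 0.27, HHAT at 0.23, DISP1 at 0.17, CDON at 0.09, BOC at 0.02, GAS1 at -0.09 and EVC at -0.19. The list's camera test gave adjusted p = 0.0573, and adjusted p = 0.75 with an estimated correlation. PTCH1 lost its call without overexpression replicate 1 or vector replicate 3 (adjusted p up to 0.0527). SMO kept its call in 1 of the 6 fits, the one without vector replicate 1, and SUFU in 0 (adjusted p up to 0.132 and 0.176).

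**Figure D4:**
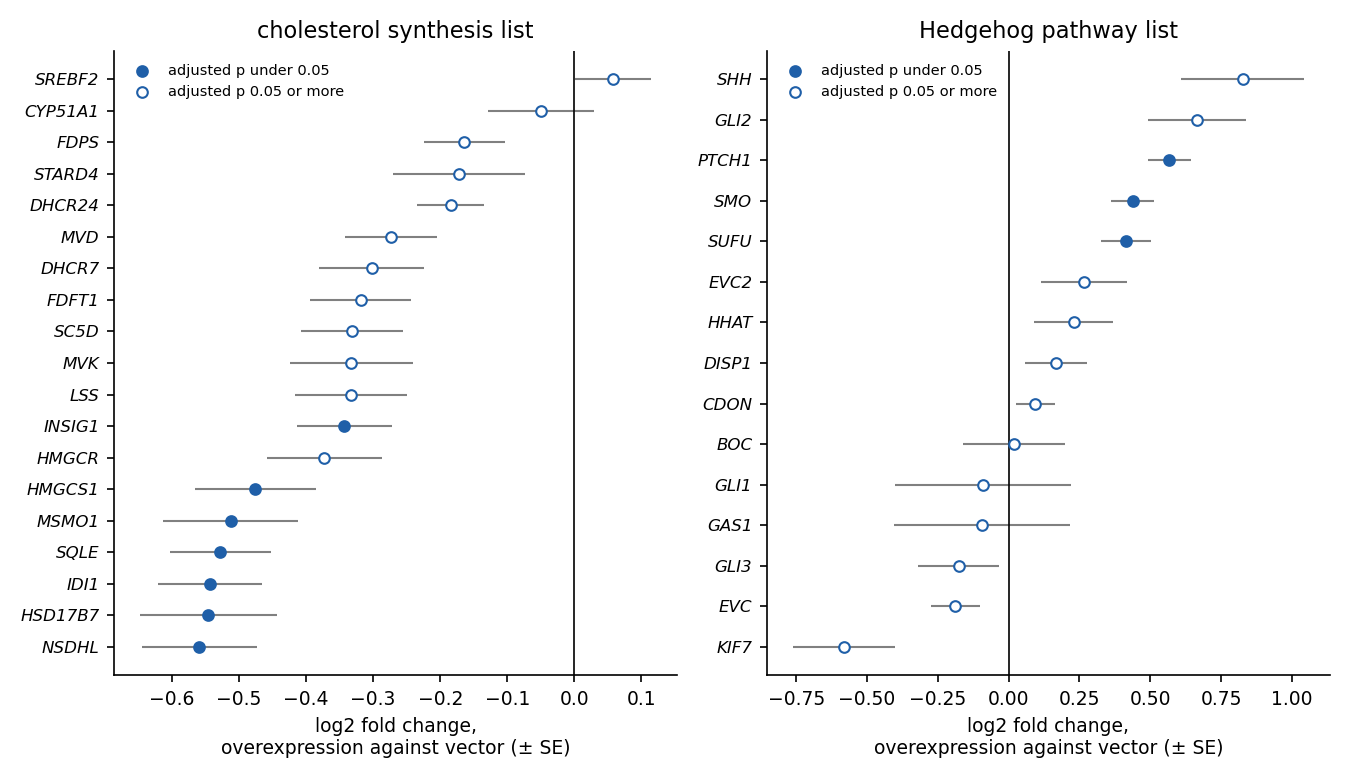
Log2 fold change (overexpression minus vector, ± SE) of the cholesterol synthesis and Hedgehog pathway genes reported here with a mean of at least 0.5 CPM. Cholesterol synthesis genes lie below 0 apart from SREBF2 at 0.06, while Hedgehog genes lie on both sides.

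Genes of hypoxia and glycolysis moved in both directions, with 4 of 20 tested members higher and 2 lower, and 9 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0527). The aldolase gene ALDOC rose by 1.13 ± 0.13 on the log2 scale (55.9 ± 7.21 against 25.5 ± 4.44 CPM, edgeR adjusted p = 0.0034), and PFKFB4, an enzyme gene of fructose 2,6-bisphosphate turnover, by 0.78 ± 0.09 (39.6 ± 1.75 against 23.1 ± 2.39 CPM, edgeR adjusted p = 0.0034). The transcription factor gene BHLHE40 fell by 1.15 ± 0.10 (11.9 ± 0.569 against 26.4 ± 1.68 CPM, edgeR adjusted p = 0.000422), as did SLC2A3. P4HA1 at 0.52 and HK2 at 0.47, named here after their values were seen, were the other higher members. HK2 lost its call with day as a block (block adjusted p = 0.128) and in all 6 fits that left out 1 library, and P4HA1 lost it without vector replicate 3. Immediate-early and MAPK output genes had 4 of 24 members lower and none higher (5 lower when adjusted over the list alone, camera adjusted p = 0.21). These were the phosphatase genes DUSP5 (-0.99 ± 0.09, edgeR adjusted p = 0.000779), DUSP1 (-0.94 ± 0.14, edgeR adjusted p = 0.0103) and DUSP4 (-0.89 ± 0.17, edgeR adjusted p = 0.0305), and the transcription factor gene EGR1 (-0.36 ± 0.06, edgeR adjusted p = 0.0216). DUSP4 and EGR1 lost the call with day as a block (block adjusted p = 0.0971 and 0.0951). DUSP1 lost its call without overexpression replicate 1, overexpression replicate 3 or vector replicate 3, with adjusted p up to 0.0714. EGR1 lost its call without any of those or vector replicate 2 (up to 0.132), and DUSP4 in all 6 fits (up to 0.149).

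Smaller numbers of calls came from other lists. Epithelial genes had 2 of 18 lower and none higher (4 lower when adjusted over the list alone, camera adjusted p = 0.21), the keratins KRT18 at -0.74 ± 0.09 and KRT8 at -0.56 ± 0.09, both kept with day as a block. NF-kappaB and cytokine genes had 1 of 15 higher, the chemokine CCL20 at 0.78 ± 0.08, and 1 lower, TNFAIP3 at -0.67 ± 0.08, an inhibitor of NF-kappaB signalling (4 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.312). ATF4 and amino acid response genes had 1 of 17 higher, ATF3 at 0.86 ± 0.08 (6 higher when adjusted over the list alone, camera adjusted p = 0.0587). Mesenchymal genes had 1 of 17 higher, FN1 at 0.38 ± 0.07, and 1 lower (2 and 2 when adjusted over the list alone, camera adjusted p = 0.637). DNA replication genes had 2 of 22 higher, E2F1 at 0.44 ± 0.08 and MCM7 at 0.31 ± 0.06 (2 when adjusted over the list alone, camera adjusted p = 0.21). KRT8, FN1, E2F1 and MCM7 were each called in 2 or fewer of the 6 fits that left out 1 library. All 4 lost the call without overexpression replicate 1, vector replicate 2 or vector replicate 3 (adjusted p up to 0.107, 0.132, 0.115 and 0.164). FN1, E2F1 and MCM7 lost the call with day as a block (block adjusted p = 0.0795, 0.0802 and 0.138).

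The p53 target DDB2 at 0.52 ± 0.11 (1 of 19), the ER chaperone PDIA4 at 0.31 ± 0.07 (1 of 16) and the histone gene H4C14 at 0.55 ± 0.10 (1 of 16) were the single higher members of their lists, and the YAP/TAZ target AXL at -0.57 ± 0.11 (1 of 14) the single lower one. Adjusted over the list alone, the counts were 3 higher for p53 targets, 3 higher and 1 lower for ER chaperones, 3 higher for histones and 1 lower for YAP/TAZ targets, with camera adjusted p = 0.637, 0.481, 0.229 and 0.361. DDB2, PDIA4, H4C14 and AXL each lost the call with day as a block (block adjusted p = 0.14, 0.118, 0.104 and 0.0991) and were called in 1 or 0 of the 6 fits that left out 1 library. They all lost it without any of the 3 overexpression replicates or vector replicates 2 or 3 (adjusted p up to 0.156, 0.182, 0.144 and 0.144). Nuclear-encoded oxidative phosphorylation genes had 1 of 23 lower, UQCRC2 at -0.29 ± 0.06, also 1 when adjusted over the list alone. The list passed the camera test (adjusted p = 0.0205, median log2 fold change -0.10), but not with an estimated correlation (adjusted p = 0.75), with day as a block (adjusted p = 0.0581) or with library size scaling (adjusted p = 0.0604). It also missed the threshold without overexpression replicate 1 (adjusted p = 0.204), overexpression replicate 3 (0.0785), vector replicate 2 (0.0563) or vector replicate 3 (0.0782). UQCRC2 lost its call with day as a block (block adjusted p = 0.122) and kept it in 1 of the 6 fits that left out 1 library, the one without vector replicate 1 (adjusted p up to 0.164).

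No member passed over all genes tested in the lists for mitosis (20 tested), interferon-stimulated genes (19), androgen receptor targets and prostate luminal genes (7), Wnt targets (13), neuroendocrine genes (6), mitochondrially encoded genes (13), ribosomal proteins (25), leukocyte markers (3) or endothelial markers (3). Their camera adjusted p was 0.775, 0.226, 0.611, 0.17, 0.85, 0.0573, 0.17, 0.637 and 0.896 in that order. Adjusted over the list alone, 2 mitosis genes were higher and 1 lower, 1 androgen receptor or luminal gene, 1 Wnt target and 1 neuroendocrine gene were higher, 1 mitochondrially encoded gene was lower, and the other 4 lists had none. Fibroblast markers had 1 of 8 higher, COL3A1, also 1 when adjusted over the list alone (camera adjusted p = 0.226), with its reads in overexpression replicates 1 and 2.

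The second comparison asked which genes changed along the days after transfection, as a slope shared by both groups. No gene passed in edgeR's test (lowest adjusted p = 0.97), with 505 of 20352 genes at an unadjusted p under 0.05, 10 genes called by DESeq2 and 0 by limma-voom. Leaving out overexpression replicate 1 or vector replicates 1, 2 or 3 gave 3, 1, 5 and 2 genes. No gene list passed either, and the lowest camera adjusted p was 0.155, for ATF4 and amino acid response genes. Without overexpression replicate 1, 4 lists passed, and without overexpression replicate 3, 1 list.

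The third comparison asked whether the effect of overexpression differed along the days. No gene passed in edgeR's test (lowest adjusted p = 0.112), with 537 genes at an unadjusted p under 0.05, 13 genes called by DESeq2 and 0 by limma-voom. Leaving out overexpression replicates 1, 2 or 3 gave 2, 16 and 2 genes, and leaving out vector replicates 1, 2 or 3 gave 30, 30 and 40. With all 6 libraries the interaction fit has 2 residual degrees of freedom, and fewer with 1 left out. The slope of the group that lost a library then passes exactly through its remaining libraries. Calls from such fits therefore say little about effects that differ along the days. The 4 genes of smallest p with a mean of at least 2 CPM were EIF3CL, RAB4B-EGLN2, SPARC and ZNF23, with differences in slope of -0.30, -4.31, -0.71 and 0.38 log2 per day, all at an adjusted p of 1. EIF3CL and RAB4B-EGLN2 were among the genes called by DESeq2, and RAB4B-EGLN2 was called by edgeR without vector replicate 1, 2 or 3, at slope differences of -2.85, -4.63 and -6.41. RAB4B-EGLN2, a read-through gene, was at 40.4, 0.297 and 0 CPM in overexpression replicates 1, 2 and 3 and at 0.254, 13.8 and 5.34 CPM in vector replicates 1, 2 and 3.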

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

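The fits without overexpression replicates 1 and 2 together were chosen only after the result was seen. The count for overexpression against vector (461, with 221 higher and 240 lower) was 108 (53, 55) with no low-count filter and 1443 (700, 743) with DESeq2. It was 162 (91, 71) and 191 (111, 80) with log2 FPKM plus 1 and plus 0.1, 74 (34, 40) with day as a block, and 181 (93, 88) with that block in limma-voom. It was 66 (29, 37) at an absolute log2 fold change of at least 1, 1060 (504, 556) at an adjusted p of 0.1, and 22 (8, 14) without overexpression replicates 1 and 2 together, where the lone overexpression library is assumed to vary like the others. Leaving out 1 library gave 54 (without vector replicate 3) to 511 (without vector replicate 1), 25 to 223 higher and 29 to 288 lower. All 461 genes kept their sign in the 6 fits that left out 1 library, which selection in the same libraries largely fixes. Of the 461, 46 kept their call in all 6 fits. RLE scaling, library size, a mean of at least 1 CPM, limma-voom and robust fitting gave 464, 500, 569, 446 and 658, sharing 457, 399, 450, 411 and 449 genes with the 461. Apart from the stricter fold, the looser threshold and the left-out libraries, the cause was not tested.

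The slope with day gave 4 genes with a mean of at least 1 CPM, 10 with DESeq2 and 0 to 5 with 1 library left out. The interaction gave 13 with DESeq2 and 2 to 40 with 1 library left out, where few residual degrees of freedom remain. The number of lists called was 2, against 0 with an estimated correlation, 0 with fry, 1 with day as a block, 1 with library size and 1 to 6 with 1 library left out. The day lists gave 0 to 4 with 1 library left out. Without overexpression replicates 1 and 2 together, log2 fold changes reversed to -0.31 for BOC, -0.03 for SLC45A3, -0.01 for NDUFB8, -0.04 for COL1A1 and -1.75 for COL1A2. With 1 library left out, BOC ran from -0.07 to 0.19, DLL3 from -0.05 to 0.15, GAS1 from -0.33 to 0.10 and GLI1 from -0.22 to 0. None of these genes was called with all 6 libraries, and COL1A1, COL1A2 and NDUFB8 were called without overexpression replicate 3 (adjusted p = 0.0471, 0.0219 and 0.0471). Of 50 called named genes, 28 kept their call with day as a block, 21 in all 6 fits with 1 library left out, 50 with DESeq2 and 41 with limma-voom, and 0 changed sign. Day as a block changed no call of the genes named by the rule or of the lists beyond those given. The cause was not tested.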

Other observations

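The enrichment, the tests of PPP3CA's paralogs and construct, the tests on overexpression replicates 1 and 2, the tests of overlapping and read-through genes and the splits of the libraries were chosen only after the result was seen. Genes of the collagen-containing extracellular matrix were enriched among those higher with overexpression, 14 of 240 where 3.38 were expected (hypergeometric adjusted p = 0.028). They included FN1, LGALS1, HSPG2, COL18A1, LTBP1 and COL3A1, and COL3A1 had its reads in overexpression replicates 1 and 2. Genes of the endoplasmic reticulum lumen (13 of 233, 3.28 expected, adjusted p = 0.0476) and of fructose and mannose metabolism (5 of 31, 0.5 expected, adjusted p = 0.0351: ALDOC, HK1, HK2, PFKFB4 and PFKL) were enriched too. Of the genes named for these terms, HSPG2, LGALS1, ALDOC and PFKFB4 kept their call with day as a block. The lumen term shares genes with the matrix term, FN1, LGALS1, COL18A1, LTBP1 and COL3A1 among them. The matrix term was lost with limma-voom (adjusted p = 0.12), no low-count filter (0.673) and log2 FPKM plus 1 or 0.1 (0.0913 and 0.26), the lumen term with these (0.164, 0.295, 0.0913 and 0.26) and robust fitting (0.0687). The metabolism term was lost with no low-count filter (0.564), a mean of at least 1 CPM (0.0616), log2 FPKM plus 1 or 0.1 (0.351 and 0.601) and robust fitting (0.0776).

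Among genes lower with overexpression, cholesterol biosynthetic process was enriched (9 of 32, 0.52 expected, adjusted p = 5.16e-06), as was ribosomal large subunit biogenesis (6 of 29, 0.47 expected, adjusted p = 0.00742: PAK1IP1, PES1, RPL26L1, RPL7, RRS1 and ZNF622, none of them called with day as a block). Sterol biosynthetic process (6 of 28, adjusted p = 0.00742) and cholesterol metabolic process (8 of 75, adjusted p = 0.0266) share genes with the first. None of the 7 terms was enriched among the 74 genes called with day as a block, where cholesterol biosynthetic process had adjusted p = 0.573. With the same block in limma-voom, 5 terms were enriched: cholesterol biosynthetic process (3.83e-08), sterol biosynthetic process (0.000708), cholesterol metabolic process (0.000535) and the matrix and lumen terms (both 0.0169). Cholesterol biosynthetic process was lost with log2 FPKM plus 0.1 (0.0776). The other lower terms were lost with log2 FPKM plus 1 or 0.1 and with no low-count filter, and large subunit biogenesis also with limma-voom (0.0707). Cholesterol biosynthetic process was also lost without overexpression replicate 1 (adjusted p = 0.107), vector replicate 2 (0.105) or vector replicate 3 (1), and the other 6 terms were each lost without each of those libraries. Fructose and mannose metabolism was lost in all 6 fits that left out 1 library (adjusted p from 0.11 to 1) and ribosomal large subunit biogenesis in 5 of them. The matrix and lumen terms were also lost without overexpression replicate 2 (0.257 and 0.117), and sterol biosynthetic process and cholesterol metabolic process without overexpression replicate 3 (both 0.0902).

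PPP3CA was about 10.2 times higher in the overexpression libraries. A change of the whole region is argued against, since 26 other tested genes within 2 Mb had a median log2 fold change of 0.128 (SE 0.157). Reads moved from the paralogs are argued against too: PPP3CB and PPP3CC together lost 1.31 CPM against a gain of 450 CPM. Reads of the overexpression construct counted at PPP3CA remain a candidate explanation that cannot be told apart from a rise of the gene, because the construct is in every overexpression library (ratio 9.38 to 10.86 by day) and gene totals carry no information on exons.

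Reads of RN7SK, RPPH1, RMRP, RN7SL1, RN7SL2, COL3A1 and COL1A2 were higher in overexpression replicates 1 and 2 than in the other libraries. A rise shared by RNA without poly(A) tails was not seen in 52 histone and small RNA genes. Their median log2 difference to the vector mean was at most -0.01 (SE 0.159) in either library. The 16 histone genes alone were at 0.025 and 0.35 in overexpression replicates 1 and 2, and the 36 small RNA genes at -0.147 and -0.038. Weaker removal of RNA without poly(A) tails stays open, since the raised noncoding RNAs lack such tails themselves. RNA from fibroblasts may be a source: 4 of 15 other fibroblast transcripts (COL1A1, COL1A2, COL6A1, COL6A2) exceeded the vector mean by at least the set share of the COL3A1 gain (5.13 CPM) in both libraries. That margin is smaller than the spread between vector libraries for COL6A1 (104 to 114 CPM) and COL6A2 (141 to 161 CPM). Passing it says little for these 2 genes. COL6A1 and COL6A2 were also above the vector mean in overexpression replicate 3 (121 and 171 against 109 and 149 CPM). In overexpression replicates 1 and 2, SPARC was at 5.53 and 1.54 CPM against a vector mean of 2.46, and COL5A2 at 21.6 and 17.7 against 19.7. THY1 was lower there, at 0.0718 and 0.0593 CPM against a vector mean of 0.331. DCN (5.17 and 1.5 CPM) and COL6A3 (1.58 and 1.5 CPM) were at 0 in replicate 3 with vector means of 0.0905 and 0.0257 CPM. This cannot be told apart from other sources, as 8 of the 16 listed genes had at least 1 CPM in vector cells and 7 were in the earlier list. For the overexpression itself, 0 of the 7 genes were at least 2-fold above the vector mean in overexpression replicate 3, but they were picked because replicates 1 and 2 stood apart, so this value decides nothing and the overexpression itself stays open.

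Calls at overlapping genes could come from reads assigned to a neighbour. Over all 152 called genes with an overlapping partner this is argued against as a general cause: partners offset at least 50% of the change in 11 (7.2%), where random partners of like expression gave a median of 6.6% and an upper percentile bound of 10.5%. Among the 26 with an absolute log2 fold change of at least 1, ENTPD1, ENTPD1-AS1, JAM3, MCAM and BIVM-ERCC5 among them, partners did so in 7 (26.9%), at the upper bound of random partners (median 15.4%, bound 26.9%), against 4 of the 126 below it. For those 7 genes moved reads cannot be told apart from changed transcription. AC007192, at 46.5%, fell just short of the mark and stays open too. At CCND2, RNF212, PLAU and MAP7 the partners changed by 0.18, 0.17, -0.12 and -0.03 CPM. The genes themselves changed by 23.3, 9.46, -42.67 and -9.47 CPM in that order. These values argue against reads moved between CCND2, RNF212, PLAU or MAP7 and their partners. Of the 5 called read-through genes, partners did so in 3, BIVM-ERCC5, MSH5-SAPCD1 and POC1B-GALNT4, too few to decide. Partners of INO80B-WBP1 and RBM14-RBM4 moved the same way as the gene (8.48 and -11.49 beside 3.33 and -8.34 CPM). BIVM-ERCC5 itself varied within the vector group, at 27.8, 0.414 and 25.8 CPM in vector replicates 1, 2 and 3. Its summed CPM with BIVM and ERCC5 varied less, at 59.9, 48.6 and 51.1.

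One hypothesis was that the circular RNA binds miR-338-3p, which might raise genes with its sites. Of 12686 expressed genes with a 3' untranslated region, 1674 held the 7-base site, and their median log2 fold change exceeded that of the rest by 0.0092, at percentile 83.7 of 239 words of the same base composition, inside their central range of -0.0172 to 0.0154. The site was in 14.6% of higher and 12.3% of lower called genes against 13.2% of all, so no rise of site genes was detected. SMO, called higher here, held the site and GLI1 did not, and single genes do not decide the hypothesis.

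Splitting the 6 libraries into 3 and 3 in all 10 ways, the real split was the 1 that gave as many as 461 genes, and the highest of the others gave 3, also among splits that part all 3 day pairs. For gene lists, 7 of the 10 splits gave as many as the real 2, and the highest other gave 8. With 10 splits no share under 0.05 can be reached.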
